A study of Homo sapiens with 8 samples.

How the data were processed

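RNA was sequenced from 8 libraries of 3 human hepatocellular carcinoma cell lines, and each condition was represented by 1 library. The libraries formed 4 pairs. PLC8024 and SNU-878 cells carried a control short hairpin (shNC) or a hairpin named sh2ADAR1, and SNU-449 and SNU-878 cells carried an empty vector (EV) or a vector for the p110 form of ADAR1. Library groups were taken from the labels. Per the labels' protocols, messenger RNA libraries were made with a KAPA kit from column-purified total RNA.

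Per the submitters' processing notes, STAR 2.5.2, RSEM 1.2.31 and build GRCh38 were used. The role of each tool and the annotation release were not given in the sources used here. The gene identifiers, with their version numbers, matched GENCODE release 29 for 52238 of the 60725 genes, and all 52238 had the same coordinates there. The deposited tables gave 1 comparison of 2 libraries each, for 60725 genes and for 199348 transcripts. Per the file headers, each table held TPM values (transcript levels scaled to a common total) for both libraries. It also held normalised read counts for both libraries, a signal that the authors had divided by 1 factor per library within each pair. The authors' deposited tables further gave a fold, as a ratio of the larger library over the smaller, a posterior probability of difference (PPDE), and a false discovery rate used like a q-value. The tool behind those comparisons was not given in the sources used here.

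The factor of each library was recovered from the spacing of its low normalised read counts. Multiplied back, the values were estimated counts with 2 decimals, of which 82.6% to 84.0% were whole within a tolerance of 0.005, so whole reads were not recovered. The summed estimated counts gave the depth of each library. Because the deposited values were normalised, the tests between conditions used limma and no count model, as the design provided for normalised values. The design also provided a count test on rounded estimated counts, and the recovered estimated counts were not tested that way. All 8 libraries were brought to a common scale by the median of ratios over all libraries for the comparison of the SNU-878 controls (EV against shNC).

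Within a pair, the log2 ratio was taken on normalised read counts with a pseudocount of 1, so each fold is on the log2(value + 1) scale, which understates the change of low genes. With 1 library per condition there was no test within a pair. A gene passed the size rule when its mean of both libraries was at least 1 TPM and its log2 ratio was at least 1 or at most -1. The same rule was applied to the SNU-878 controls as a background with no ADAR1 construct. Both controls also differ in construct and deposited table, so their difference does not measure variation within a pair. The fold changes of pairs were compared across genes by Pearson's r and Spearman's rho, and overlaps were set against the product of both list sizes over the genes compared. Pairs shared no control library.

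Across lines, limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) of all 8 libraries, with the pair as a block and a mean-variance trend. Genes with at least 10 normalised counts in at least 2 libraries were kept, which left 18632 genes. The 3 tests were the knockdown in PLC8024 and SNU-878, the overexpression in SNU-449 and SNU-878, and the ADAR1 direction over all 4 pairs, with 2, 2 and 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Pairing came from the labels, since the libraries of a pair are of 1 cell line and 1 deposited table. The procedure was tested on simulated data in which genes were changed by known amounts. At a log2 change of 1 the knockdown, overexpression and direction tests recovered 4.8%, 1.6% and 12.9% of the changed genes. At 2 they recovered 53%, 53% and 83.3%, and at 3 they recovered 90.3%, 86.1% and 90.3%, each among 18632 genes. The simulation gave all pairs a dispersion of 0.05 and the same change in each pair of a test. The real ratios had a median absolute deviation of 0.571 in PLC8024 and 0.195 in the SNU-878 knockdown. Recovery in these data may therefore be lower.

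Gene lists for interferon response, antigen presentation, mitophagy, autophagy, stem cell markers, cell cycle, signalling, metabolism, cell types and large gene families were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of these lists, 34 had at least 5 members among the tested genes. Within a pair, a list's median was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, and the members with a mean of at least 1 TPM entered. Across lines, lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, all from limma. At an estimated correlation camera has only the residual degrees of freedom, 2 or 3 here and 1 for differences between lines. It could then hardly call a list, so a missing call there does not by itself argue against one. The preset can also be too low for lists whose members move together. The estimated correlation was 0.899 for MHC class I presentation and 0.823 for mitochondrially encoded messenger RNAs in the knockdown. It was 0.691 for ribosomal proteins in the overexpression. With such correlations the p-values at the preset are too small. Double-stranded RNA sensing in the overexpression had an estimated correlation of -0.027, under 0.01, yet its unadjusted camera p went from 0.0118 to 0.113. Camera compares a list with the other genes, and fry asks whether its members move one way on balance. Counts of members past the threshold were taken over all genes and adjusted over the list alone.

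Named genes were ADAR, the 5 highest and 5 lowest genes of each pair that passed the size rule and had a real symbol, the 10 rising and 10 falling genes with the smallest p of each test across lines that moved the same way in each pair, and up to 4 members per list, the 2 highest and the 2 lowest. Where no gene passed the adjusted threshold, the genes with the smallest p were taken and are said not to pass. Genes on the Y chromosome that the rule took are left out, clone-named genes are not described, and 1 gene that the rule took is not reported here. Shared sequence was measured by aligning transcripts of each named gene to those of other genes with BLAST 2.17.0, at 95% identity and a word size of 28. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

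Alternatives tried were a pseudocount of 0.1, mean floors of 0.1 and 5 TPM, a log2 limit of 1.5, a median log2 ratio of 0 in each pair, transcripts in place of genes, the cell line as block, other filters, and each pair left out in turn. A correction for GC content and gene length was added after the data had been seen. So was a search of 3' untranslated regions (UTRs) for 7-base words, over 10618 protein-coding genes with a mean of at least 5 TPM.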

Results

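The series measured messenger RNA in hepatocellular carcinoma lines in which ADAR1, the adenosine deaminase that edits double-stranded RNA, was lowered or raised. Its stated interest is ADAR1 editing in stemness and mitophagy of liver cancer. PLC8024 and SNU-878 cells were compared with and without an ADAR1 hairpin, and SNU-449 and SNU-878 cells with and without a vector for ADAR1 p110, the shorter protein form. Each of the 8 conditions had 1 library, so no difference within a line has a replicate check, and p-values across lines rest on a spread pooled over all 4 pairs. Whether libraries came from separate cultures was not given in the sources used here. Depth was similar. The libraries held between 26836653 and 31566232 estimated counts. Between 13663 and 15145 genes per library reached 1 TPM. Libraries of a pair correlated across genes with r of 0.953 in PLC8024, 0.989 in both SNU-878 pairs and 0.982 in SNU-449, and the SNU-878 controls of the hairpin and vector experiments correlated at 0.983.

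ADAR, the targeted gene, was lower in both knockdown libraries and higher in both overexpression libraries, as the labels say. The gene (ENSG00000160710.15) lies on the minus strand of chromosome 1 from 154582062 to 154627999 in GRCh38. It stood at 139.31 TPM in PLC8024 shNC and 51.05 TPM in the knockdown. The log2 ratio was -1.08 on normalised read counts, a smaller drop than the TPM values give. Here and below the log2 ratios are those of normalised read counts and can differ from those of the TPM values. In SNU-878 the values were 132.7 and 84.13 TPM, a log2 ratio of -0.73. Overexpression brought ADAR from 80.19 to 219.05 TPM in SNU-449 and from 138.91 to 283.85 TPM in SNU-878, with log2 ratios of 1.24 and 0.87. The SNU-878 controls differed by 0.20. Among genes at 1 TPM or more, ADAR ranked at the 11.2 and 4.67 percentile of the knockdown ratios and at the 98.2 and 97.5 percentile of the overexpression ratios. The limma coefficient was -0.90 (SE 0.21, n = 2 pairs) for knockdown, 1.05 (SE 0.21, n = 2 pairs) for overexpression and 0.98 (SE 0.13, n = 4 pairs) for the ADAR1 direction, and none passed after adjustment over all genes, with adjusted p of 0.672, 1 and 0.868.

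The ADAR transcripts differed in their response. ENST00000368471, which encodes the 931-residue form, went from 72.17 to 21.49 TPM in the PLC8024 knockdown and from 64.33 to 34.91 TPM in SNU-878. ENST00000368474, which encodes the 1226-residue form known as p150, went from 9.18 to 11.77 TPM and from 20.04 to 14.71 TPM. Under overexpression the largest gain was listed for ENST00000529168, a model annotated with 1200 residues and so not with the 931-residue form. It spans 154584809 to 154602626 and ends short of the full 3' UTR. It stood at 1.57 and 79.41 TPM in SNU-449 and at 13.91 and 126.69 TPM in SNU-878. ENST00000368471 went from 42.21 to 70.22 TPM in SNU-449 and from 71.56 to 88.57 TPM in SNU-878. These transcripts share most of their sequence, so the split of reads between them is uncertain. In the authors' deposited table the false discovery rate for ADAR was 0.952 in PLC8024, 0.478 in the SNU-878 knockdown, 0.229 in SNU-449 and 0.000825 in the SNU-878 overexpression.

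**Figure D1:**
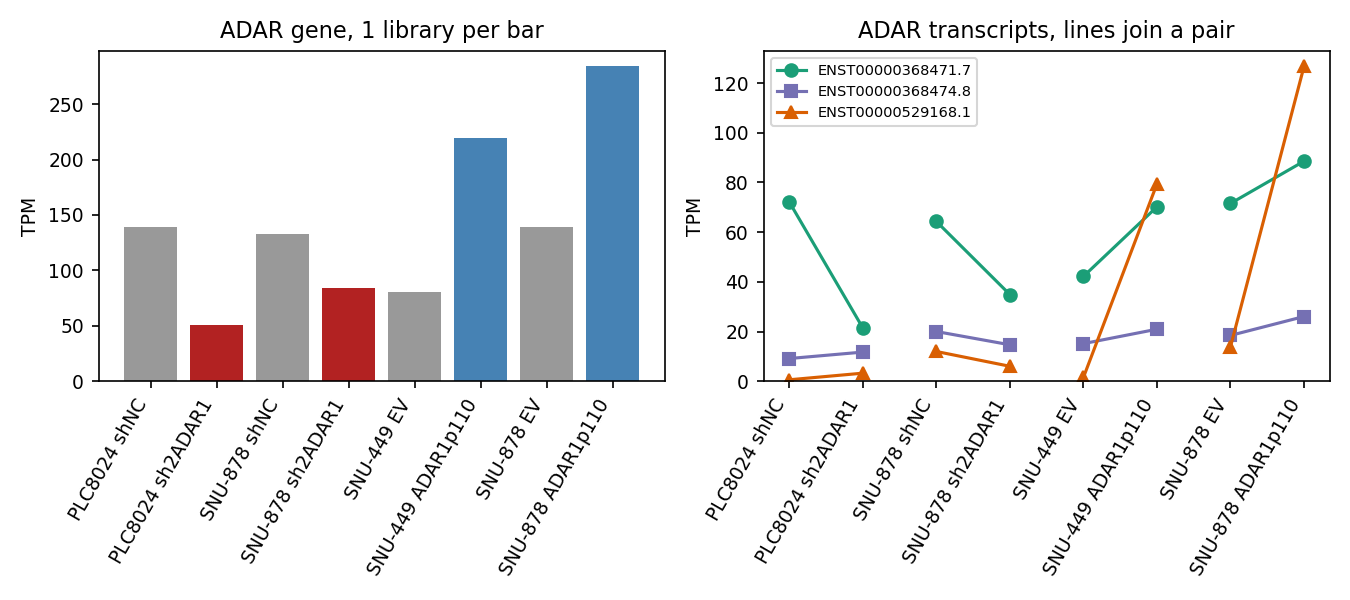
ADAR in each library in TPM, with gene values as bars on the left and 3 transcripts as points on the right, where lines join the libraries of a pair. Gene values lie between 51.05 TPM in the PLC8024 knockdown and 283.85 TPM in the SNU-878 overexpression.

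The PLC8024 knockdown library differed from its control in more genes than any other pair. Of 15076 genes at 1 TPM or more, 2153 were higher and 1934 lower by the size rule, which is 27.1%. In the SNU-878 knockdown 244 were higher and 340 lower, or 3.87% of 15102 genes. SNU-449 with ADAR1 p110 had 504 higher and 862 lower, or 9.75% of 14004 genes, a balance that turned to 306 higher and 289 lower at a floor of 5 TPM, and SNU-878 with ADAR1 p110 had 281 higher and 332 lower, or 4.08% of 15022 genes. The same rule took 1067 genes, or 7.03% of 15184, between both SNU-878 controls, more than the 584 and 613 genes of the SNU-878 pairs. Those controls came from the hairpin and vector experiments, so this count may also hold differences between experiments. The PLC8024 pair also differed in RNA features. Transcripts annotated as retained introns made up 8.94% of TPM in its control and 6.20% in its knockdown, and mitochondrial transcripts made up 9.21% and 12.4% of estimated counts. The control stood apart from the other libraries, whose retained-intron share was at most 7.60%. Protein-coding genes held 93.2% of its counts, against 95.3% to 96.8% elsewhere. Mitochondrial ribosomal RNA held 4.56%, against at most 2.83% elsewhere. In the authors' deposited table, with a false discovery rate under 0.05, 539 genes were up and 540 down in PLC8024, 79 and 155 in the SNU-878 knockdown, 142 and 380 in SNU-449, and 182 and 206 in the SNU-878 overexpression.

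**Figure D2:**
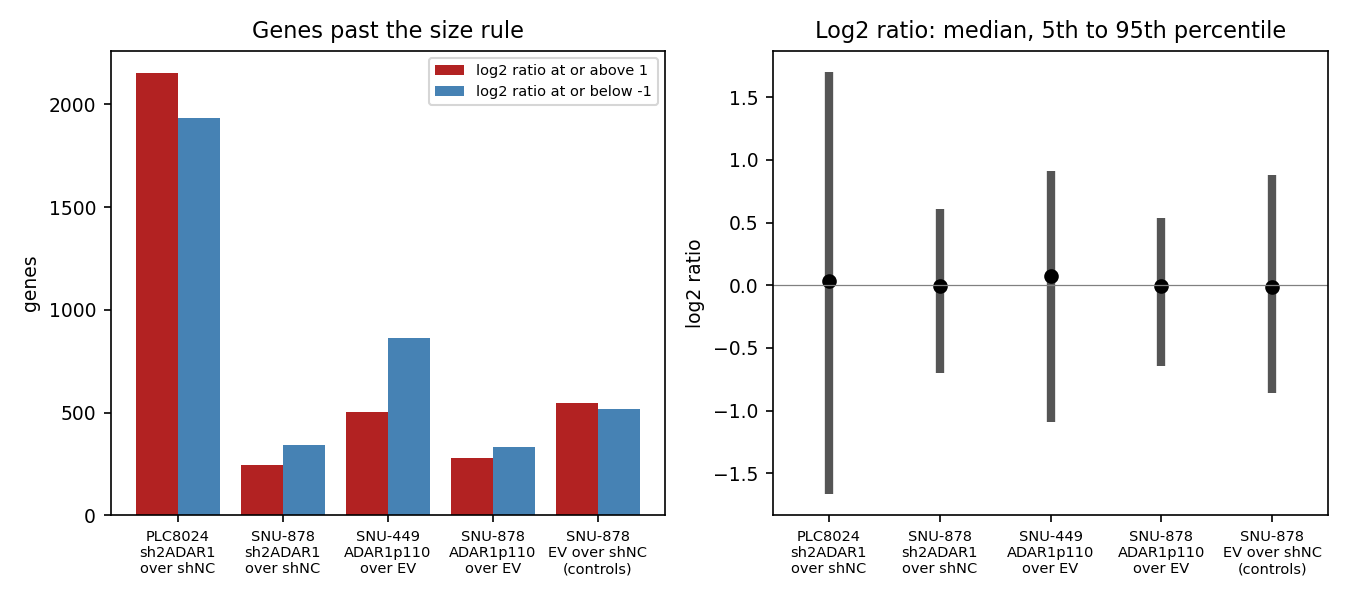
Bars on the left count the genes at or above a log2 ratio of 1 or at or below -1 in each comparison of 1 library with 1 library, and the right panel gives the median log2 ratio as a point and the 5th to 95th percentile as a bar. The PLC8024 pair has 4087 such genes and the SNU-878 controls have 1067.

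Several of the extreme genes of the PLC8024 knockdown were present in 1 library of the pair only. ALPI, an intestinal alkaline phosphatase, stood at 7.73 TPM in the control and was listed at 0 in the knockdown. APOL3, an interferon-inducible apolipoprotein L, stood at 5.94 TPM and KRT80, an epithelial keratin, at 2.43 TPM, and both were listed at 0 in the knockdown. SLC16A6, a monocarboxylate transporter family member, and CCR6, a chemokine receptor, were listed at 0 in the control and stood at 2.4 and 2.6 TPM in the knockdown. Of the CCR6 transcript 74.9% is shared with an overlapping gene and of the SLC16A6 transcript 32.0% with other genes, so both are uncertain. The other extremes, TICAM2, TMEM265, CTAG1A, MAGED4 and IKBKGP1, have near-identical copies or overlapping genes, and their values are uncertain.

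In the SNU-878 knockdown, DHRS2, a mitochondrial short-chain dehydrogenase, stood at 7.62 TPM in the control and 49.83 TPM in the knockdown (log2 ratio 2.76), against -1.04 in PLC8024. DSCR4-IT1, a noncoding transcript, was listed at 0 in the control and stood at 2.03 TPM. RMRP, the RNA of a mitochondrial RNA processing complex, has 2 entries at nearly the same place on chromosome 9. One went from 9.32 TPM to a listed 0 while the other stood at 0.72 and 14.38 TPM, and the split between them is uncertain. XAGE1A, TGIF2-C20orf24, HIST1H2AD and RPL23AP47 also share sequence with copies and are uncertain.

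With ADAR1 p110 in SNU-449, EVI2B and EVI2A, neighbouring genes within an intron of NF1, stood at 0.29 and 0.18 TPM in the control and at 16.02 and 8.0 TPM in the overexpression (log2 ratios 5.76 and 5.19). BMPER, a secreted regulator of bone morphogenetic proteins, stood at 0.3 and 7.61 TPM (4.20), and BCL2A1, an anti-apoptotic target of NF-kB, at 0.08 and 2.07 TPM (3.99). KCNJ15, an inward rectifier potassium channel, was lower, at 5.56 and 0.4 TPM (-3.96). In SNU-878, GZMB, the protease granzyme B, stood at 0.29 and 3.54 TPM (3.80) and MYBPH, a myosin-binding protein, at 0.5 and 6.68 TPM (3.66). GPR146, an orphan receptor, stood at 3.27 and 0.22 TPM (-4.15), with 79.6% of its transcript shared with an overlapping gene. Of the EVI2B, EVI2A and BCL2A1 transcripts 27.5%, 28.2% and 27.7% are shared with other genes, which makes their values uncertain. In the other line, EVI2B and EVI2A (SNU-878) and GZMB and MYBPH (SNU-449) were listed at 0 in both libraries and cannot be compared. BMPER, BCL2A1 and KCNJ15 had ratios of 1.62, 1.03 and -0.87 in SNU-878, with BMPER and BCL2A1 listed at 0 in its control, and GPR146 had -2.51 in SNU-449. BMS1P12, CDRT4, PDXDC2P, GP1BB, SLC2A3P1, GAGE2E, MAGED4, TMEM265, ZNFX1-AS1_2, RPL23AP21 and RPL23AP24 completed the extremes and are uncertain for shared sequence.

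The knockdown across PLC8024 and SNU-878 asked which genes move in both lines when ADAR1 is lowered. No gene passed in limma (smallest adjusted p 0.672 of 18632 genes), and 1110 had an unadjusted p under 0.05, where 932 would be taken by chance. The genes named here therefore did not pass. The lowest p belonged to PLBD2, a lysosomal phospholipase B-like protein on chromosome 12 (113358566 to 113391625), which stood at 78.08 and 17.66 TPM in PLC8024 and at 27.06 and 9.29 TPM in SNU-878 (-1.91, SE 0.20). CALU, a calcium-binding protein of the endoplasmic reticulum, had -1.13 (SE 0.19), ZNF385A, an RNA-binding zinc finger protein, had -1.94 (SE 0.32), and NMI, an interferon-inducible partner of STAT proteins, had -1.67 (SE 0.30). FAF2, NUBP2, POLDIP3, MORF4L1, TMTC1 and PPP1R32 completed the lower group, with MORF4L1 and PPP1R32 uncertain because 41.2% and 40.9% of their transcripts are shared. On the higher side, PECAM1, an endothelial adhesion molecule, stood at 2.99 and 18.12 TPM in PLC8024 and at or near 0 in SNU-878. TGM2, tissue transglutaminase, stood at 32.13 and 168.81 TPM in PLC8024 but below 1 TPM in SNU-878 (1.88, SE 0.42). ACTG1, cytoplasmic gamma actin, had 0.86 (SE 0.20), AFAP1, an actin filament binding protein, had 1.00 (SE 0.23), and ALG5, an enzyme of N-glycosylation, had 1.21 (SE 0.29). Of the 10 genes in the lower group, 7 hold the 7-base word CCCATCC in the 3' UTR, as do 15.1% of the 10618 genes searched. The word was picked from the same knockdown ratios, so this count is no separate support for it.

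Among 34 gene lists, camera called 5 in the knockdown, and none held with an estimated correlation or by fry. With 2 residual degrees of freedom, camera at an estimated correlation had little power to call any list. The 13 mitochondrially encoded messenger RNAs rose as a list, with a median of 0.98 and all 13 above 0 (adjusted p = 5.46e-08, and adjusted p = 0.843 with an estimated correlation). None of them passed over all genes and 6 rose when adjusted over the list alone. MT-CO3, a cytochrome oxidase subunit, had log2 ratios of 2.76 in PLC8024 and 0.38 in SNU-878, while MT-ND1, a complex I subunit, had 0.45 and 0.23. The ribosomal RNAs MT-RNR1 and MT-RNR2 did not share this, with -0.36 and -0.72 in PLC8024. The SNU-878 controls differed in the same messenger RNAs by a median of 0.79, with all 13 above 0 in the EV library.

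**Figure D3:**
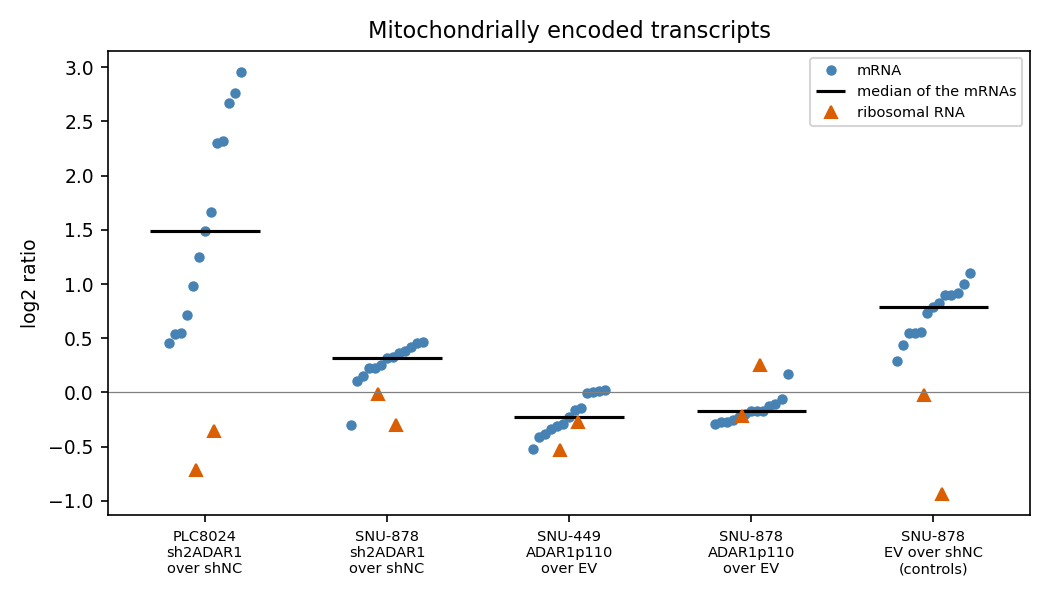
Log2 ratios of the mitochondrially encoded transcripts in each comparison of 1 library with 1 library, with messenger RNAs as circles, their median as a line and ribosomal RNAs as triangles. The medians are 1.49 and 0.31 in the knockdown pairs, -0.23 and -0.17 in the overexpression pairs and 0.79 between the SNU-878 controls.

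The genes of MHC class I presentation fell as a list in the knockdown test, with a median of -0.68 and 15 of 16 members below 0 (camera adjusted p = 4.87e-05, and adjusted p = 0.843 with an estimated correlation). PSMB9, an immunoproteasome subunit, had log2 ratios of -3.31 in PLC8024 and -0.26 in SNU-878, and HLA-B, a classical class I heavy chain, had -2.16 and 0.21. Interferon-stimulated genes had a median of -0.49 with 25 of 35 below 0 (adjusted p = 0.0117, and adjusted p = 0.843 with an estimated correlation). IFI27 had -3.25 and -0.37, while MX1, an antiviral GTPase, was higher in both lines, at 0.72 and 1.01, and IFITM3, which restricts virus entry, was at 0.13 and 2.02. Mesenchymal genes had a median of -0.57 with 18 of 21 below 0 (adjusted p = 6.07e-04, and adjusted p = 0.843 with an estimated correlation). The matrix proteins TGFBI and SPARC were lower in both lines, at -2.17 and -1.96 and at -1.78 and -2.13, and the transcription factor ZEB1 stood at -0.21 and 1.82. Wnt targets had a median of 0.70 with 14 of 17 above 0 (adjusted p = 0.00812, and adjusted p = 0.843 with an estimated correlation), led by DKK1 and APCDD1. DKK1, a secreted Wnt inhibitor, went from 1.68 to 24.25 TPM in PLC8024 and from 148.02 to 116.95 TPM in SNU-878, and APCDD1 had ratios of 3.28 and 0.05. No member of these lists passed over all genes or adjusted over the list alone.

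All 5 calls were lost without the PLC8024 pair. The knockdown is then 1 pair with 1 residual degree of freedom and a spread taken from the overexpression pairs, so the loss alone does not show that PLC8024 differs. The adjusted p became 0.197 for the mitochondrially encoded list, 0.520 for MHC class I presentation, 0.198 for interferon-stimulated genes, 0.341 for mesenchymal genes and 0.833 for Wnt targets, and the lists of MHC class I presentation, interferon-stimulated genes and Wnt targets turned direction in camera. Within SNU-878, over members at 1 TPM or more, the list medians were 0.12 for MHC class I presentation, 0.07 for interferon-stimulated genes and -0.02 for Wnt targets, the last of which was 0.03 over all 17 tested members. When genes holding CCCATCC were left out, a choice made after the data were seen, 3 lists were called, and those of Wnt targets and interferon-stimulated genes were not, each at an adjusted p of 0.0628.

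The lists closest to the stated interest of the series were not called in the knockdown. The mitophagy list had a median of 0.01 with 15 of 29 above 0 (camera adjusted p = 0.588). SQSTM1, the autophagy receptor p62, stood at -0.65 and -0.27, and AMBRA1, a regulator of Parkin-independent mitophagy, at 0.83 and 0.33. Stem cell markers of liver cancer had a median of 0.27 with 17 of 26 above 0 (adjusted p = 0.169). ICAM1, an adhesion molecule used as such a marker, was higher in both lines at 1.30 and 1.36, while SOX2 stood at 3.58 and -0.81 and the transporter ABCG2 at 0.10 and -1.66. Core autophagy genes had a median of -0.08 with 11 of 30 above 0 (adjusted p = 0.239), among them ULK1, the initiating kinase, at -2.94 and 0.24. Transcripts known to be edited had a median of -0.25 with 7 of 20 above 0 (adjusted p = 0.218).

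Overexpression of ADAR1 p110 across SNU-449 and SNU-878 also gave no gene past the threshold in limma (smallest adjusted p 0.666), and 452 genes had an unadjusted p under 0.05, fewer than the 932 taken by chance. The genes with the smallest p are named without having passed over all genes. BNIP3 and BNIP3L, mitophagy receptors of the outer mitochondrial membrane, stood at 222.33 and 96.75 TPM and at 111.43 and 55.86 TPM in SNU-449, and at 95.1 and 44.68 TPM and at 45.16 and 24.77 TPM in SNU-878. Their coefficients were -1.16 (SE 0.21) and -1.11 (SE 0.22), and of the BNIP3 transcript 34.4% is shared with a pseudogene and other genes. PFKFB4, a regulator of glycolysis, had -1.59 (SE 0.28). TPD52L1, a member of the tumour protein D52 family, had the smallest p among the named lower genes, from 120.95 to 30.96 TPM in SNU-449 and from 218.28 to 87.87 TPM in SNU-878 (-1.71, SE 0.25). RGS5, a pericyte marker and regulator of G protein signalling, had -1.67 (SE 0.28), NLGN4X, a synaptic adhesion protein, -2.17 (SE 0.46), and MMP11, a matrix metalloproteinase, -2.44 (SE 0.55). The higher group held RGS4 at 2.65 (SE 0.51), the protease-activated receptor F2RL1 at 2.05 (SE 0.45), MYPN, a sarcomere protein, at 2.03 (SE 0.50), BMPER at 2.91 (SE 0.70), and CD68, whose transcript is fully shared with overlapping genes and is uncertain. The SNU-878 EV library was itself higher than shNC in several of the lower genes, with log2 ratios of 1.14 for BNIP3, 1.54 for BNIP3L, 1.74 for PFKFB4, 3.32 for RGS5 and 4.67 for NLGN4X.

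Camera called 9 lists in the overexpression, 6 upward and 3 downward, and none held with an estimated correlation (smallest adjusted p = 0.839 with an estimated correlation) or by fry. Genes of glycolysis and hypoxia fell as a list, with a median of -0.35 and 21 of 25 below 0 (adjusted p = 3.39e-07), and 1 member, PFKFB4, fell when adjusted over the list alone. CA9, a hypoxia-induced carbonic anhydrase, had -1.61 in SNU-449 and -1.96 in SNU-878, and HK2, hexokinase 2, had 1.40 and -0.38. The SNU-878 controls differed in this list by a median of 0.53. NF-kB and cytokine genes rose as a list with all 15 above 0 and a median of 0.77 (adjusted p = 2.13e-06). The cytokine IL6 had 1.68 and 1.03, and LIF 0.68 and 1.70. Mitotic genes of the G2/M list had a median of 0.28 with 24 of 25 above 0 (adjusted p = 6.56e-06), including AURKA, a mitotic kinase, at 1.03 and 0.39. YAP targets had a median of 0.33 with 15 of 17 above 0 (adjusted p = 0.00114), led by ANKRD1 at 2.46 and 0.77 and CYR61 at 0.59 and 1.17. The SNU-878 controls differed in YAP targets by a median of -0.58, more than this change.

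The cytosolic ribosomal proteins had a small median of 0.13 with all 83 above 0 (camera adjusted p = 6.44e-06, and adjusted p = 0.839 with an estimated correlation). Against random lists matched on expression their median lay at percentile 79.6 in SNU-449 and 51.2 in SNU-878, where 49 of 81 were above 0. The G1/S list had a median of 0.15 with 22 of 25 above 0 (adjusted p = 0.00407) but -0.02 within SNU-878, double-stranded RNA sensing had 0.19 with 14 of 17 above 0 (adjusted p = 0.0445), and zinc finger genes had -0.09 with 308 of 497 below 0 (adjusted p = 0.0445). Between the SNU-878 controls the medians were -0.11 for ribosomal proteins and -0.14 for zinc finger genes. IFIH1, the cytosolic sensor MDA5, stood at 0.77 and 0.58. The fibroblast markers had a median of -0.70 with 6 of 8 below 0 (adjusted p = 0.0129), and RGS5 fell when adjusted over the list alone. The medians of this list went opposite ways, at -1.09 in SNU-449 and 0.41 in SNU-878, and the mixed form of fry, which disregards direction, called it (adjusted p = 0.0370). Each of these had adjusted p of at least 0.839 with an estimated correlation. Without the SNU-449 pair, which leaves 1 overexpression pair and a spread from the knockdown pairs, 7 of the 9 calls were lost, with adjusted p of 0.0602 for G2/M, 0.0594 for NF-kB, 0.765 for ribosomal proteins, 0.917 for G1/S, which turned direction, 0.252 for double-stranded RNA sensing, 0.569 for zinc finger genes and 0.772 for fibroblasts. Without the SNU-878 pair of this test 3 were lost, with 0.0973 for YAP targets, 0.111 for double-stranded RNA sensing and 0.0863 for zinc finger genes, and the fibroblast call was also lost without either knockdown pair, at 0.0937 and 0.0712.

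The mitophagy list was not called in the overexpression, with a median of 0.09 and 21 of 29 above 0 (camera adjusted p = 0.299). Its members went both ways. BNIP3 and BNIP3L fell when adjusted over the list alone, and SQSTM1, at 0.93 and 0.39, and the deubiquitinase USP15, at 0.46 and 0.35, were higher without passing. As given above, the SNU-878 EV library exceeded shNC in BNIP3 and BNIP3L by about as much as they fell or more, and part of the BNIP3 transcript is shared. Stem cell markers had a median of 0.12 with 14 of 26 above 0 (adjusted p = 0.741). ABCG2 was higher at 1.77 and 1.11, and the pluripotency factors POU5F1, at -0.99 and -1.96, and SOX2, at -1.02 and -0.96, were lower, none of them passing.

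**Figure D4:**
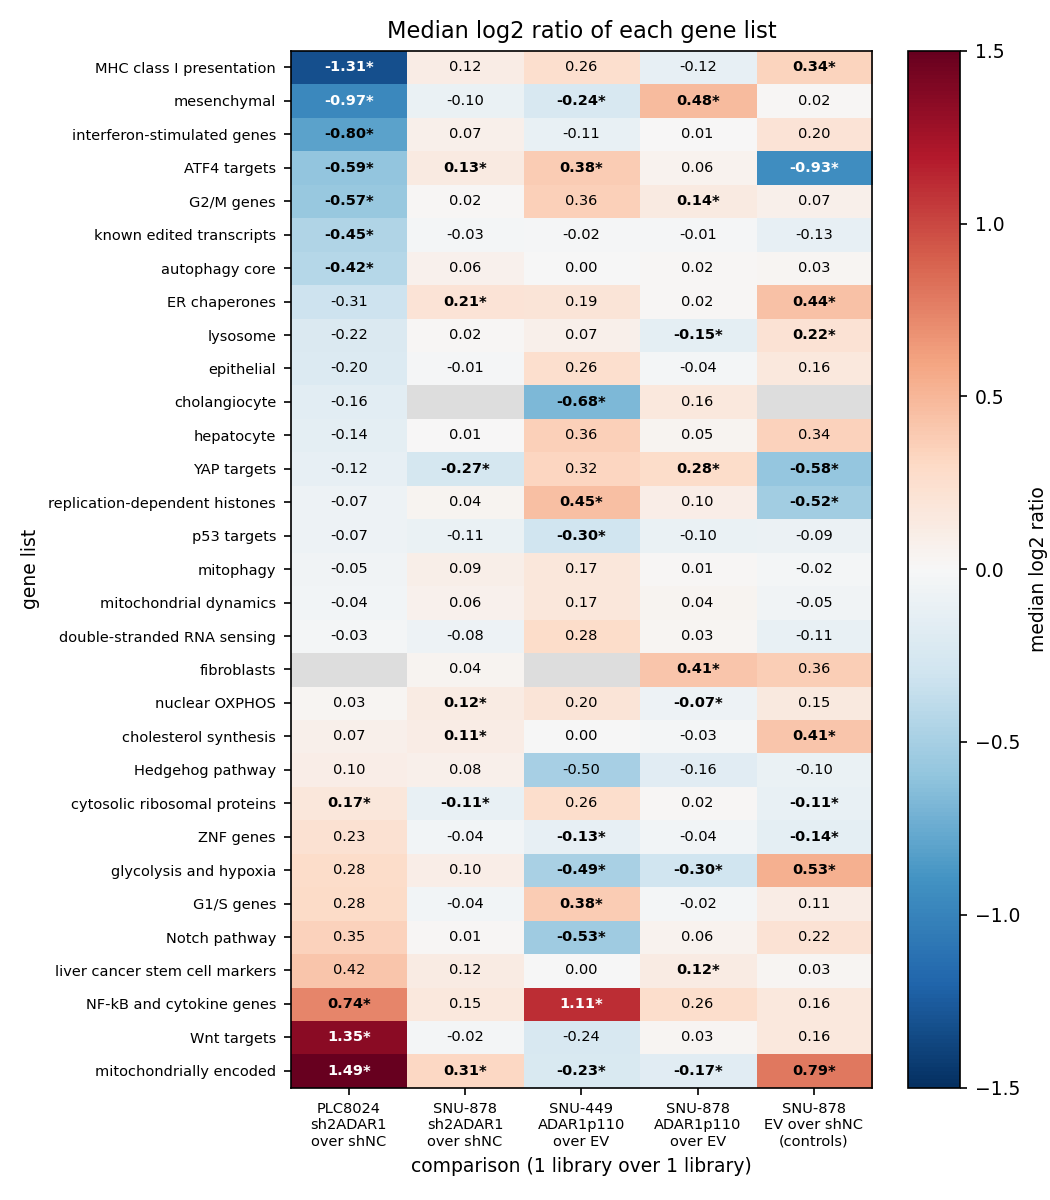
Median log2 ratio of the members of each gene list (vertical axis) in each comparison of 1 library with 1 library (horizontal axis), as colour and as printed value, where a star marks a median outside the middle 95% of 10000 random lists matched on expression and grey marks lists with under 5 members. MHC class I presentation is lowest in PLC8024 at -1.31, and 11 of 30 lists are starred between the SNU-878 controls.

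The ADAR1 direction test combined all 4 pairs and asked which genes follow ADAR1 whether it is lowered or raised. No gene passed in limma (smallest adjusted p 0.868), and 723 had an unadjusted p under 0.05, fewer than the 932 taken by chance. After ADAR, the genes with small p on the rising side included CYR61, a matricellular YAP target, with log2 ratios of -1.19 and -0.63 in the knockdowns and 0.59 and 1.17 in the overexpressions (0.90, SE 0.16). CAV1, the caveolar coat protein, had 1.14 (SE 0.27), TRIP6, a focal adhesion protein, 0.84 (SE 0.19), and TTI2, a partner of PIKK kinases, 0.94, which is uncertain because 37.2% of its transcript is shared. On the falling side SLC2A1, the glucose transporter GLUT1, had 1.01 and 0.40 in the knockdowns and -0.51 and -1.15 in the overexpressions (-0.77, SE 0.18). TM7SF2, a sterol reductase, had -0.76 (SE 0.17) and FER1L4, a pseudogene transcript, -1.51 (SE 0.28). These did not pass, and the SNU-878 controls differed by -1.61 in CYR61, -1.30 in CAV1 and 1.06 in SLC2A1.

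Camera called 9 lists by ADAR1 direction, 6 upward and 3 downward, with no call at an estimated correlation (smallest adjusted p = 0.738 with an estimated correlation) or by fry. Of the 20 different splits of the libraries, the real one included, 12 called at least 9 lists, so the number of calls does not set the ADAR1 direction apart. Of the 9 lists called by ADAR1 direction, 3 held without each pair in turn. The mitochondrially encoded messenger RNAs moved against ADAR1 (median -0.53, all 13 below 0, adjusted p = 7.41e-07), as did glycolysis and hypoxia genes (-0.32, 21 of 25 below 0, adjusted p = 8.19e-05), and G2/M genes moved with it (0.27, 22 of 25 above 0, adjusted p = 9.61e-06), though not in the SNU-878 knockdown, where their median was 0.02 with 14 of 25 above 0. UBE2C, a mitotic ubiquitin-conjugating enzyme, stood at -1.24 and -0.03 in the knockdowns and at 0.58 and 0.17 in the overexpressions. Glycolysis and hypoxia genes had a median of only 0.04 in the SNU-878 knockdown. Between the SNU-878 controls the median of that list differed by more, in size, than its median by direction. The mitochondrially encoded messenger RNAs differed by a median of 0.79 between those controls. YAP targets had a median of 0.17 with 13 of 17 above 0 (adjusted p = 0.00325), of which CYR61 rose when adjusted over the list alone. That call was lost without the SNU-878 overexpression pair (adjusted p = 0.0569), and the SNU-878 controls differed in this list by -0.58.

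The remaining calls by direction were each lost without at least 1 pair, and their adjusted p was at least 0.738 with an estimated correlation. MHC class I presentation (median 0.37, 15 of 16 above 0, adjusted p = 4.20e-04) and mesenchymal genes (0.27, 17 of 21 above 0, adjusted p = 0.00204) lost their call without the PLC8024 pair, at 0.973 and 0.476, where MHC class I presentation turned direction. In SNU-449 the mesenchymal median of -0.24 went against the call, as did the MHC class I medians of both SNU-878 pairs, at 0.12 in the knockdown and -0.12 in the overexpression. ATF4 targets (0.13, 18 of 24 above 0, adjusted p = 0.00551), with DDIT3, the stress factor CHOP, at -3.31, 0.13, 0.99 and 0.34 over the pairs, lost theirs without PLC8024 at 0.972 and without SNU-449 at 0.0908. Wnt targets (-0.35, 13 of 17 below 0, adjusted p = 0.0298) lost it at 0.973, turning direction, and 0.125. The SNU-878 controls differed by -0.93 in ATF4 targets and 0.34 in MHC class I presentation. Ribosomal proteins (0.05, 60 of 83 above 0, adjusted p = 0.0298) lost it at 0.800 without SNU-449, turning direction, 0.180 without the SNU-878 knockdown and 0.0550 without the SNU-878 overexpression. Medians against these calls were 0.13 for ATF4 targets in the SNU-878 knockdown, -0.02 and 0.03 for Wnt targets in the SNU-878 knockdown and overexpression, and 0.17 for ribosomal proteins in PLC8024. The mitophagy list had a median of -0.01 with 13 of 29 above 0 (adjusted p = 0.751), and the median and the test differed in sign. Stem cell markers had a median of -0.15 with 10 of 26 above 0 (adjusted p = 0.361).

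Fold changes were hardly related between the knockdown lines and weakly related between the overexpression lines. Across 12870 genes, which are not independent replicates, the knockdown ratios of PLC8024 and SNU-878 had r of 0.027 and rho of 0.038. By the size rule 42 genes were lower in both, where the list sizes give 17.6, and 29 were higher in both, where they give 17.7. Genes lower in PLC8024 and higher in SNU-878 numbered 29 against 12.7. The overexpression ratios of SNU-449 and SNU-878 had r of 0.152 and rho of 0.242 over 12454 genes, 59.5% of them with the same sign, with 18 genes higher in both against 3.64 and 27 lower in both against 6.93. Opposite pairs of directions were also above the product, at 19 against 4.37 and 21 against 5.77. Within SNU-878, knockdown and overexpression ratios had r of 0.0023 and rho of -0.042 over 14400 genes, and 16 genes were higher in the knockdown and lower in the overexpression against 2.34, while 15 were higher in both against 1.74.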

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

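Both tests of the mitochondrial pattern were chosen only after the result was seen, the tests of the PLC8024 spread were chosen once that spread was known, with the outcomes to look for written down before each was run, and the differences between lines had no outcome written down. The values given are differences between lines in the response to the same construct. Each line's response is 1 pair of single libraries, so the spread comes from the pairs of the other construct, and no p-value here measures variation between repeats of a line. For single genes, the test of the difference in limma has 1 residual degree of freedom and called 0 genes for knockdown and 0 for overexpression, with 2727 and 260 genes at an unadjusted p under 0.05. Lists were compared with camera at the preset correlation, at an estimated correlation, and with fry. At the preset correlation 10 of 34 lists were called for knockdown and 14 for overexpression. None was called with an estimated correlation, where the smallest adjusted p was 0.882 and 0.899, and by fry 1 list was called for knockdown and 0 for overexpression.

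Between the PLC8024 and SNU-878 knockdowns, the median difference (PLC8024 minus SNU-878, log2) was -1.32 for MHC class I presentation (adjusted p = 2.46e-07) and -1.03 for interferon-stimulated genes (2.40e-05). ER chaperones differed by -0.64 (5.96e-04), ATF4 targets by -0.58 (3.75e-04) and G2/M genes by -0.51 (0.00419). HSPA5, the chief chaperone of the endoplasmic reticulum, stood at -1.82 and 0.31. Core autophagy genes differed by -0.45 (0.0154) and lysosomal genes by -0.35 (0.0145). Mitochondrially encoded messenger RNAs differed by 1.21 (3.75e-04), Wnt targets by 1.19 (0.00134) and ribosomal proteins by 0.27 (0.0145). YAP targets differed by 0.52 in fry (adjusted p = 0.0131) and not in camera (0.503).

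Between the overexpressions (SNU-449 minus SNU-878), NF-kB and cytokine genes differed by 0.83 (adjusted p = 0.00271), nuclear genes of oxidative phosphorylation by 0.33 with 60 of 63 above 0 (8.27e-05), ribosomal proteins by 0.25 with 83 of 83 above 0 (8.27e-05) and G1/S genes by 0.29 (0.00108). Lysosomal genes differed by 0.25 (0.0462), G2/M genes by 0.26 and ATF4 targets by 0.22 (both 0.0477). Mesenchymal genes differed by -0.88 (0.00108), where FN1, fibronectin, stood at -0.27 and 2.69, and cholangiocyte markers by -0.68 (0.0303). Fibroblast markers differed by -0.97, markers of an embryonic kidney line by -0.88, Hedgehog genes by -0.53, Notch genes by -0.44 and Wnt targets by -0.28, each with an adjusted p of 0.0477.

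The log2 ratios of the PLC8024 pair were spread more widely than those of any other pair. A trend with GC content and gene length was argued against as the whole cause, since 3557 genes passed the size rule after it was removed, against 1158 in the next pair. Cells of the other lines mixed into the knockdown library were argued against by 16 genes typical of those lines, whose median level was 0.0332% of the level there, and a library of another line by 72 of 88 genes typical of PLC8024 (81.8%) that reached 1 TPM. Both checks looked at levels in the knockdown library and did not test the control, which stood apart in its RNA features. More unspliced sequence in the control remains a candidate explanation, because the share of retained-intron transcripts differed by a factor of 1.442 in this pair and by at most 1.076 elsewhere. The control held the higher share, while single-exon genes were higher in the knockdown (median 0.45 against 0.02 for other genes), which goes against extra genomic sequence in the control. A response of this line to ADAR1 loss is untested and also stays open.

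Mitochondrially encoded messenger RNAs moved against ADAR in all 4 pairs by their medians. Variation between libraries of 1 line may account for part of this, since the SNU-878 controls alone differed by 0.7892, more than the medians of 3 of the 4 pairs. Those controls also differ in construct and deposited table, so their difference does not measure variation within a pair. In the PLC8024 knockdown the ribosomal RNAs MT-RNR1 and MT-RNR2 were lower, at -0.3584 and -0.7182, so the measured mitochondrial transcripts did not all rise. Its control stood apart, with mitochondrial ribosomal RNA at 4.56% of counts against at most 2.83% elsewhere. The libraries were made for messenger RNA, so ribosomal RNA reads may depend on the preparation. This check therefore cannot decide whether all mitochondrial transcripts rose in the cells. An effect of ADAR1 on the mitochondrially encoded messenger RNAs was not tested apart from variation between libraries and stays open.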

How the results depend on the processing

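The correction for GC content and length and the removal of genes with the word CCCATCC were chosen after the data were seen. The pair of libraries was already the block in each test. DESeq2, voom and a comparison of TMM with size factors were not run, although the recovered estimated counts could have been used for them. The knockdown, overexpression and direction tests gave 0 genes under all 11 alternatives each, and the 10 alternatives for lists per pair kept their counts within 1.5 times. In the knockdown, overexpression and direction tests 0 lists were called with an estimated correlation and 0 with fry. The few residual degrees of freedom left camera at an estimated correlation little power. For lists with a high estimated correlation, the p-values at the preset may be too small. Leaving out 1 pair in turn gave 4 to 10 lists for knockdown, 3 to 10 for overexpression and 7 to 12 for direction, where a test left with 1 pair of its construct takes its spread from the other pairs, and without genes holding the word the knockdown called 3. A log2 limit of 1.5, which takes fewer genes by construction, gave 1985 genes in PLC8024, 214 and 279 in the SNU-878 knockdown and overexpression, 505 in SNU-449 and 384 between the SNU-878 controls. A floor of 0.1 TPM, which admits more low genes, gave 7656, 2797, 2828, 3906 and 3217 in that order, and a floor of 5 TPM gave 2370, 170, 159, 595 and 382. At that floor 306 genes were higher and 289 lower in SNU-449, against 504 and 862. Removal of the GC and length trend gave 356 genes in the SNU-878 knockdown and 402 in the overexpression. ADAR in SNU-449 had 1.17 with the pair's median set to 0. The correlation of both knockdowns was 0.0010 with a pseudocount of 0.1 and 0.0579 without the GC and length trend. That of both overexpressions was 0.0905 at a floor of 0.1 TPM, 0.233 at 5 TPM, 0.178 without the 1% of extreme genes, 0.0837 with a pseudocount of 0.1 and 0.170 without the GC and length trend. Within SNU-878 the correlation of knockdown and overexpression turned to -0.0918 at 5 TPM and -0.0290 without the extreme genes. Depth limits the ratios of genes under 1 TPM, which rest on few reads. The cause was not tested where none is named.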

Other observations

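The count of genes over other splits of the libraries was chosen as a test only after the result was seen, and the search for words in 3' UTRs was not among the planned analyses. Several lists not described so far were not called in the knockdown and overexpression tests. Hepatocyte genes had medians of -0.10 and 0.00 (camera adjusted p = 0.509 and 0.742) and epithelial genes 0.07 and -0.01 (0.918 and 0.643). Genes of cholesterol synthesis had 0.10 and -0.07 (0.525 and 0.219), p53 targets -0.05 and -0.16 (0.525 and 0.207), replication-dependent histones -0.10 and 0.22 (0.432 and 0.0860) and mitochondrial dynamics 0.04 and 0.12 (0.525 and 0.207). Immune and endothelial markers, with 5 measured members each, were not called (0.212 and 0.781 in the knockdown). In SNU-878 the EV and shNC controls differed in ATF4 targets by a median of -0.93 and in cholesterol synthesis by 0.41, with no ADAR1 construct in either library.

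Genes lower in both knockdown pairs were searched for a shared sequence. Among 7-base words of ADAR transcripts, CCCATCC in the 3' UTR went with the lowest ratios, with z of -13.1 in SNU-878 and -3.49 in PLC8024 and a combined z of -11.75, against -4.11 for the lowest word in the overexpression pairs. In SNU-878 it was also the lowest of all 16326 words scored, whether in ADAR or not. The next was CCATCCA, an overlapping word, at -10.5. Of the genes below -1 in the SNU-878 knockdown, 36 of 92 (39.1%) held the word, against 15.1% of all 10618 genes, and of those below -1 in both knockdowns 11 of 27 did. These counts come from the ratios that picked the word and are no separate support for it. In the PLC8024 knockdown the share was 18.5%, below the 20.9% (87 of 416) in the SNU-449 overexpression, which has no hairpin and where the word had a z of -2.84. The word occurs in ADAR on chromosome 1 at 154602595 to 154602601 in exon 2 and at 154584170 to 154584176 in the 3' UTR, and at 154586864 to 154586870 in exon 5 of 1 further transcript model. Seed pairing of the short hairpin is a candidate explanation for part of the decreases in SNU-878 and stays open for PLC8024, where the z lies within the range of its other words, whose lowest is -4.00. The hairpin sequence was not given in the sources used here.

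The number of genes lower in both knockdowns, 42, was 2.38 times the product of the list sizes. A bound of 2 had been set beforehand for calling such an overlap more than unrelated lists would give, and that bound was wrong, because genes lower in PLC8024 and higher in SNU-878 exceeded their product by a like factor of 2.283, while genes higher in PLC8024 and lower in SNU-878 numbered 40 against 24.6. Genes that vary readily could enter any such list, so a shared response to lower ADAR1 and an overlap of unrelated lists cannot be told apart here.

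Grouping by ADAR1 direction was compared with other splits of the 8 libraries. With the pair as a block, 32 splits make 20 different fits, of which only 8 part every pair as the real one does and the others part 2 pairs. The splits are too few for a share under 0.05. For single genes the real split called 0 and the highest other split 1, so all 20 gave at least as many by construction. For gene lists the real split called 9 and the highest other split 12, and 12 of the 20 gave as many, among them 5 of the 8 that part every pair.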
